A study of Mus musculus with 19 samples.

How the data were processed

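Gene expression was measured by RNA sequencing of the left prelimbic cortex of mice in 4 groups. Per the labels' protocols, mice received MK-801 (0.2 mg/kg) or saline by daily intraperitoneal injection for 2 weeks. In 1 group of each kind, ferumoxytol nanoparticles were injected once into the left prelimbic cortex and the mice were placed under a pulsed magnetic field, together called c-MSST. Libraries were made from total RNA with a stranded kit, per the labels' protocols, and tissue was taken on the third day after surgery, per the series' design text. Each library was put in its group by its title, giving 6 Control, 5 Control+c-MSST, 4 SCZ (MK-801) and 4 SCZ+c-MSST libraries. The labels do not say whether the groups without c-MSST had surgery; if they had none, the comparisons of c-MSST hold the effects of surgery and injection as well. The labels give no strain, sex, batch or time of tissue collection.

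The authors deposited a table of estimated counts per gene and a table of FPKM values, both with 1 column per library. Per the submitters' processing notes, fastp 0.19.5, STAR 2.7.7a, Picard 2.18.29 and StringTie 1.3.5 were used with the mouse build mm10. The notes give neither the order of the steps nor the annotation, and whether the counting used strand is not given in the sources used here. The deposited counts were whole numbers as found, so none was rounded. They were proportional to the FPKM values within a library (absolute log2 departure 0.00293 at the 99th percentile and 1.96 at most, over 10886 genes with a mean above 500 counts). They were treated as estimated counts and not as tallied reads. The proportionality does not settle this, because tallied reads over a fixed gene length would give it as well. The deposited FPKM values were scaled by the authors to gene length and library depth, and 11 gene names in that table had been turned into dates and were turned back. The count table listed 20938 genes, of which 2327 had no count in any library. None of the 15 mitochondrially encoded genes was in it, so their share was not computed. Library totals ran from 50140626 to 82416746 counts. A count of 0 allows a level of up to 3 counts, which is 0.0349 to 0.0620 CPM at these depths, for counting error only. Genes in near-identical copies, such as the haemoglobin genes, overlapping genes and antisense genes are uncertain where the counting step could split their reads, and 114 genes with a median of at least 1 CPM fell below 10% of their median in some library.

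Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were kept by filterByExpr on the 4 groups, which left 16417, libraries were normalized by TMM, and 1 quasi-likelihood model with a coefficient per group was fitted to all 19 libraries (glmQLFit, robust). The 5 contrasts tested with glmQLFTest were SCZ against Control, Control+c-MSST against Control, SCZ+c-MSST against SCZ, SCZ+c-MSST against Control, and the interaction, which is the effect of c-MSST in MK-801 mice minus that in saline mice. P values were adjusted by Benjamini and Hochberg, and a gene was called changed at an adjusted p under 0.05. Of 45 gene lists, 43 had at least 3 tested members and were tested with limma's camera (limma 3.58.1) at its preset correlation between genes, with camera at an estimated correlation and with fry beside it, all adjusted over the lists. A list's score in a library was the mean of its members' log2 CPM (prior count 2), each centred on its mean over the 19 libraries, and scores and the level of Gabre were compared by exact permutation tests, two-sided. Where comparisons share libraries, correlations of their fold changes were set beside 100 simulated sets of groups with no effect, 2000 permutations of the libraries, both on log2 CPM, and splits of the shared libraries.

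The groups, contrasts, tests, thresholds, gene lists and the rule for the genes named below were chosen before the data were examined. That rule took Gabre and every tested GABA-A receptor subunit; the 12 genes with the smallest p in each direction of a comparison at an adjusted p under 0.05 and a mean of at least 1 CPM, leaving out predicted names; and, for each list that passed camera or held a called gene, up to 4 called members, or otherwise the 2 members with the highest mean CPM, given as values. Genes named outside this rule, after their values were seen, were Arc, Dusp1, Npas4, Cops2, Drd1, Drd2, Zic1, Zic4 and Lhx8. Some genes that the rule took are not reported here. A list of 7 septal and medial forebrain markers and all tests on list scores were added after the levels of Zic1 and Zic4 had been seen.

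Alternatives set beforehand were DESeq2 1.42.0 (Wald test) and its size factors, upper-quartile normalization, limma voom with quality weights, no filter on low counts, a filter of at least 1 mean CPM, the replicate number as a block, 1 surrogate variable (sva 3.50.0), limma on log2 of the deposited FPKM values with pseudocounts of 1 and 0.1, fits of only the groups compared, each library left out in turn, and the SCZ libraries split so that none was shared. Alternatives added after seeing the data were the Control libraries split in the same way, tissue scores as covariates, leaving out Control replicates 2 and 3 together, and leaving out the 114 genes above. The steps were tested on simulated counts for the same 16417 genes, libraries and totals with 200 genes changed, drawn independently of one another. The changed genes were drawn from those with an average of at least 1 CPM, and the libraries were given no shared differences in tissue. The shares below are therefore not known to hold for genes as low as Gabre, or for libraries whose tissue differs. At a 2-fold change, 88.1% of changed genes were recovered for SCZ against Control, and 79.1% for Control+c-MSST against Control. The share was 85.1% for SCZ+c-MSST against SCZ, 82.1% for SCZ+c-MSST against Control and 74.6% for the interaction. At a 1.5-fold change the shares were 79.1%, 62.7%, 65.7%, 65.7% and 41.8%. Same-group libraries were compared by a chi-square statistic per degree of freedom, which was 29.2 to 110 over 37 pairs where sampling noise gives about 1, so no library was a copy of another of its group; pairs across groups were not compared in this way. The position of Gabre was taken from GENCODE M21 on GRCm38, which is mm10.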

Results

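RNA from the left prelimbic cortex of mice was sequenced in 19 libraries from 4 groups. The SCZ group had received MK-801, a blocker of the NMDA receptor used to model schizophrenia, and the Control group saline. The other two groups, SCZ+c-MSST and Control+c-MSST, had also received c-MSST, in which iron oxide nanoparticles are placed in the prelimbic cortex and a pulsed magnetic field is applied. Total counts were 50140626 to 66818266 in the 6 Control libraries and 60577337 to 72866386 in the 5 Control+c-MSST libraries. They were 65498768 to 82416746 in the 4 SCZ libraries and 66828543 to 75090222 in the 4 SCZ+c-MSST libraries. SCZ libraries had more counts on average (73156348 ± 6970804 counts, SD, n = 4) than Control libraries (61081467 ± 6534894 counts, n = 6; exact permutation p = 0.0286, two-sided). This difference did not pass after adjustment (adjusted p = 0.171), nor did any other of the 12 tests of totals, genes detected and the share of the 20 most counted genes.

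Markers of neighbouring brain regions varied widely between libraries. Drd2, a dopamine receptor of striatal neurons, ran from 1.3 CPM in Control+c-MSST replicate 6 to 101.1 CPM in SCZ+c-MSST replicate 3. The score of 12 striatal neuron markers averaged 0.94 in the 8 libraries of MK-801 mice and -0.68 in the 11 of saline mice (exact permutation p = 0.00449, adjusted p = 0.0135). Zic1, a transcription factor of the septum and medial forebrain, stood at 34.5 to 51.6 CPM in Control replicates 2, 4 and 5 and SCZ replicates 2, 3 and 5, and at 16.9 CPM or less in every other library. The score of 7 septal and medial forebrain markers averaged -0.38 in the 9 libraries with c-MSST and 0.34 in the 10 without (exact permutation p = 0.0276, adjusted p = 0.0551). Ttr, made in the choroid plexus, stood at 1607 CPM in Control replicate 2, 150 CPM in Control replicate 3 and at most 7.78 CPM elsewhere. The score of choroid plexus and ependymal markers averaged -0.76 with c-MSST and 0.68 without (exact permutation p = 0.000639, adjusted p = 0.00383). The 6 score tests were two-sided and chosen after the marker levels were seen. The remaining ones had an exact permutation p of 0.0643 (septal, MK-801 against saline), 0.900 (striatal, c-MSST) and 0.866 (choroid plexus, MK-801).

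**Figure D1:**
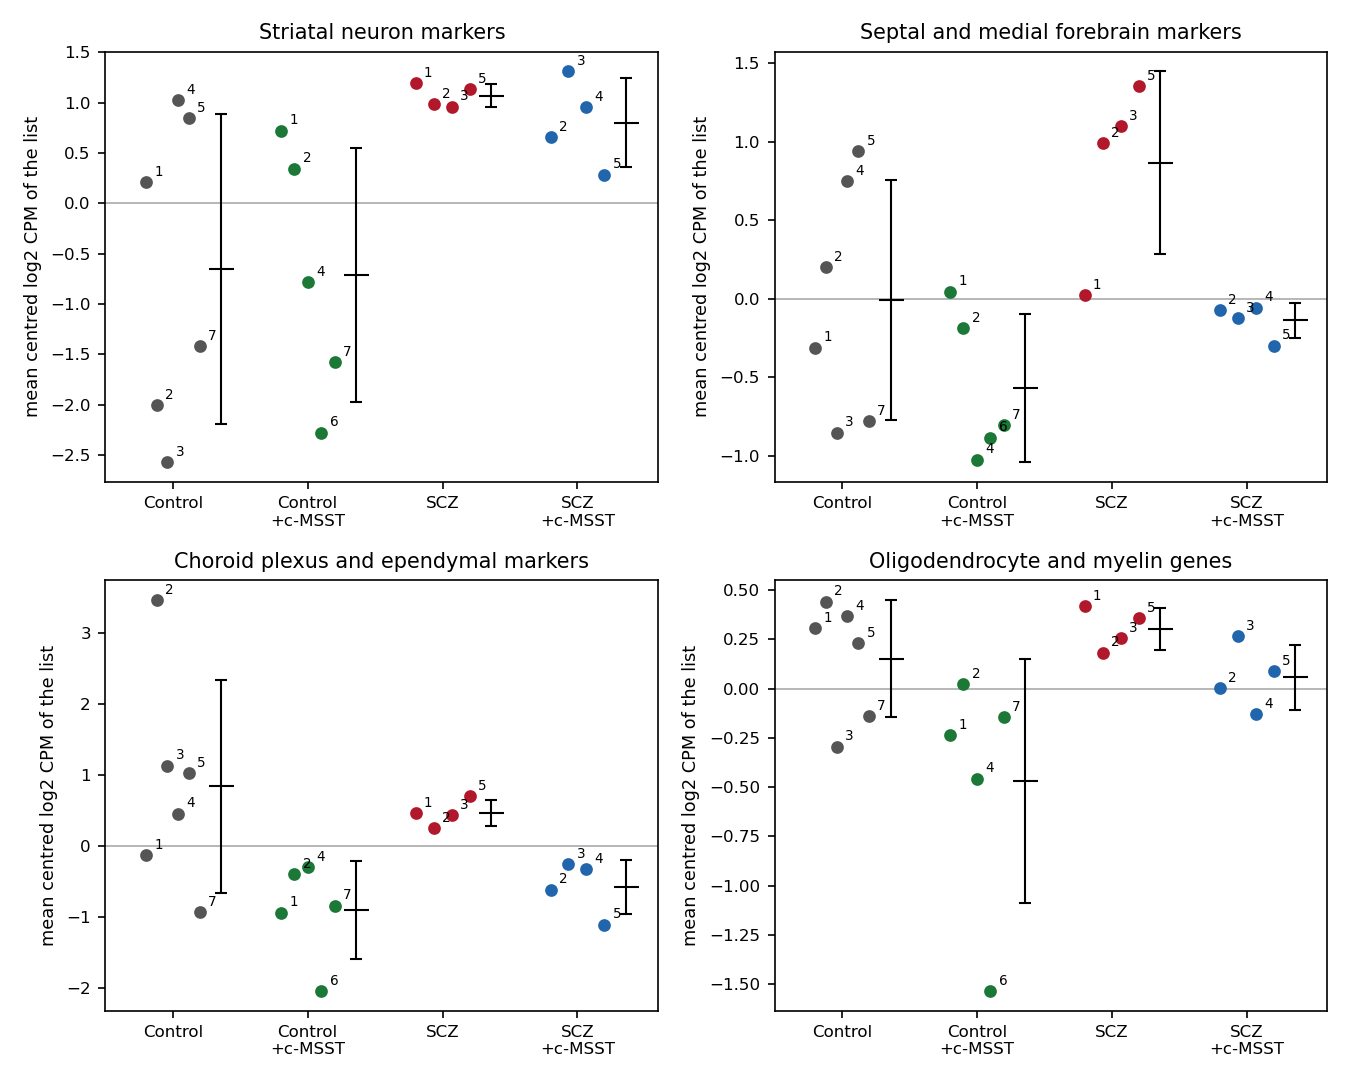
Each point is the marker score of 1 library, the mean log2 CPM of the list's genes centred on the 19 libraries, by group, for striatal, septal, choroid plexus and myelin genes. The striatal score averaged 0.94 in libraries of MK-801 mice and -0.68 in those of saline mice.

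The comparison of SCZ with Control asks what MK-801 changed in the prelimbic cortex. Immediate early genes, which neurons switch on with activity, fell as a list, with 18 of 19 members at a negative log2 fold change, a median of -0.61 and a camera adjusted p of 1.07e-11 (adjusted p = 0.267 with an estimated correlation). By library, their score differed by -0.53 (exact permutation p = 0.0238, adjusted p = 0.114 over 32 score tests chosen after the data were seen). Egr1 stood at 171 ± 27.3 CPM (SD, n = 4) in SCZ and 239 ± 57.9 CPM (n = 6) in Control. Homer1 had a log2 fold change of -0.10 (SE 0.11, adjusted p = 0.720). Arc, named after its values were seen, stood at 71.5 ± 9.71 CPM against 159 ± 55.3 CPM (log2 fold change -1.15, SE 0.26, adjusted p = 0.148). Corticosteroid response genes also fell as a list (13 of 14 negative, median -0.43, camera adjusted p = 1.26e-10; adjusted p = 0.0793 with an estimated correlation). Their score differed by -0.42 (exact permutation p = 0.019, adjusted p = 0.114 over the same score tests). Klf9, induced by glucocorticoids, stood at 235 ± 30.6 CPM against 266 ± 17.4 CPM, and Zbtb16 had a log2 fold change of -0.64 (SE 0.24). Ribosomal protein genes rose slightly (70 of 75 positive, median 0.12, camera adjusted p = 4.80e-12; adjusted p = 0.477 with an estimated correlation), with Rpl4 and Rpl3 the most abundant members. Striatal markers rose (12 of 12 positive, median 1.13, camera adjusted p = 1.30e-07; adjusted p = 0.477 with an estimated correlation), together with the striatal score given above, and Ppp1r1b had a log2 fold change of 1.13 (SE 0.60).

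By edgeR, 0 of 16417 genes passed an adjusted p under 0.05 in SCZ against Control, while 2219 had an unadjusted p under 0.05 (1000 higher, 1219 lower) where 821 are reached by chance. The smallest adjusted p was 0.0649, for Cops2, a subunit of the COP9 signalosome. DESeq2 called 243 genes, limma voom 0 and limma on FPKM values 1. Without Control replicate 4 edgeR called 94 genes, without Control replicate 5 it called 14, without SCZ replicate 1 it called 3 and without SCZ replicate 3 it called 1. Adjusted over the list alone, 12 immediate early genes and 10 corticosteroid response genes were lower, against 0 over all genes.

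Further lists, 8 in all, passed camera in SCZ against Control, none of them with an estimated correlation (adjusted p = 0.267 to 0.602). Nuclear oxidative phosphorylation genes such as Atp5b and Atp5a1 were higher in 18 of 18 (median 0.09, adjusted p = 0.000287), endothelial markers in 12 of 14 (0.11, adjusted p = 0.0184). So were genes of GABA synthesis and transport in 9 of 13 (0.04, adjusted p = 0.0226). Astrocyte markers were lower in 9 of 12 (median -0.10, adjusted p = 0.0226), postsynaptic scaffold genes in 12 of 16 (-0.07, adjusted p = 0.0243) and presynaptic genes in 13 of 16 (-0.12, adjusted p = 0.0362). Dopamine and serotonin receptors were higher in 9 of 15 (median 0.28, adjusted p = 0.0309), a list that holds the striatal markers Drd1 and Drd2 and moved with the striatal score. With that score as a covariate, chosen after seeing the data, the adjusted p was 0.839 for this list and 0.228 for the GABA-A, GABA synthesis and presynaptic lists. With the striatal, septal and choroid plexus scores together, 7 of the 12 lists no longer passed, these 4 and the postsynaptic, astrocyte and striatal ones (0.0813 to 0.991). The striatal list could hardly pass there, because its own genes make up the striatal score. Higher too were GABA-A receptor subunits in 11 of 16 (median 0.13, adjusted p = 0.0498). The GABA-A list passed fry (adjusted p = 0.0291). Its camera call was lost without SCZ replicates 1, 3 or 5 (0.0598, 0.0570 and 0.0789) and Control replicates 1, 2 or 7 (0.0812, 0.0758 and 0.0835). Without SCZ replicate 5 the calls of endothelial, GABA synthesis, and dopamine and serotonin receptor genes (0.0789 for each), postsynaptic (0.111) and presynaptic genes (0.308) were lost. Without Control replicate 1 those of postsynaptic (0.143) and presynaptic genes (0.0947) were lost, and without Control replicate 2 that of astrocyte markers (0.0792). Without Control replicate 7 postsynaptic (0.0791), presynaptic (0.271) and dopamine and serotonin receptor genes (0.0592) no longer passed, nor did the latter without Control replicate 3 (0.0772).

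**Figure D2:**
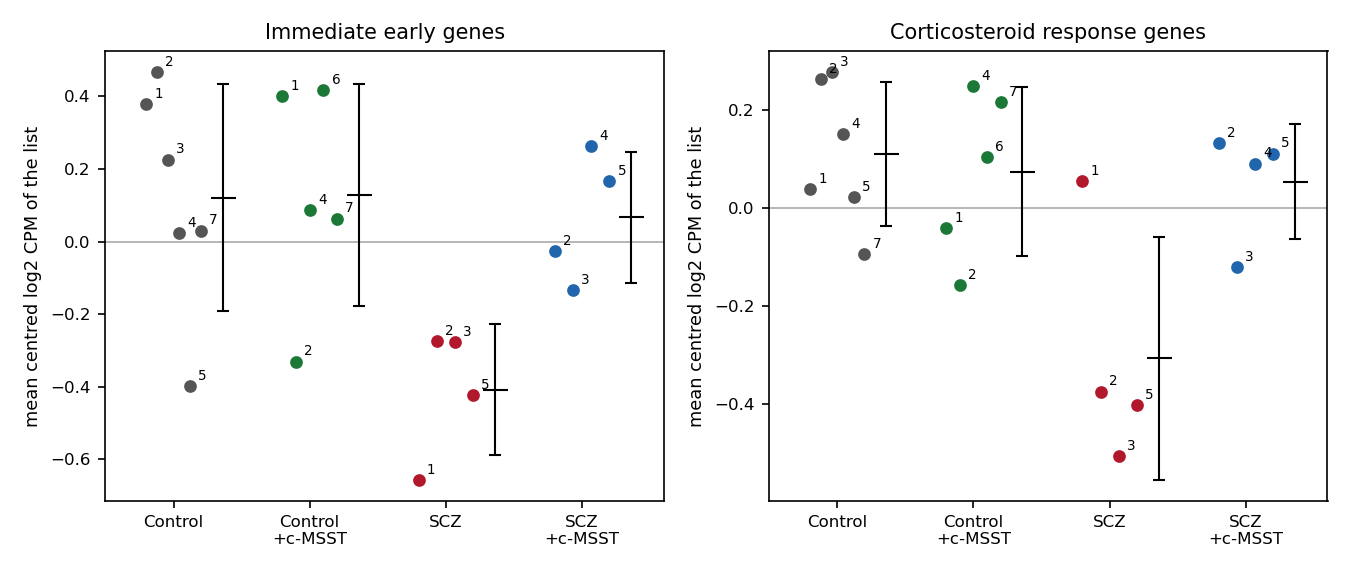
Each point is the score of 1 library for immediate early genes and for corticosteroid response genes, by group, in mean log2 CPM centred on the 19 libraries. The immediate early score averaged -0.41 ± 0.18 (SD, n = 4) in SCZ and 0.12 ± 0.31 (n = 6) in Control.

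The comparison of Control+c-MSST with Control asks what c-MSST changed in mice without MK-801. Of 16417 genes, 54 changed by edgeR, 38 higher and 16 lower, by small amounts (median absolute log2 fold change 0.35, range 0.17 to 5.11). Il33, an alarmin cytokine held by oligodendrocytes and astrocytes, fell from 24.1 ± 2.31 CPM (SD, n = 6) to 15.7 ± 1.97 CPM (n = 5; log2 fold change -0.62, SE 0.09, adjusted p = 0.014). Gatm, an enzyme of creatine synthesis, fell from 67.2 ± 7.90 to 49.2 ± 4.08 CPM (-0.45, SE 0.08, adjusted p = 0.0211). Neurl1a, a ubiquitin ligase of synapses, rose from 155 ± 8.59 to 191 ± 8.82 CPM (0.30, SE 0.05, adjusted p = 0.021). The synaptic vesicle proteins Svop and Rab26 rose by 0.39 (SE 0.07) and 0.34 (SE 0.06) on the log2 scale. The chemokine Cxcl12 rose from 49.2 ± 5.84 to 65.3 ± 4.97 CPM (0.41, SE 0.07, adjusted p = 0.0335). Ccdc80, Ccdc3, Lrrc3, Trp53i11, Kif26a, Tmem132a, Tmem121b and Arhgdia also rose, by 0.78, 0.81, 1.08, 0.41, 0.49, 0.42, 0.32 and 0.19. Tdrd3, Anxa5, Kif5b, Myo6, Trp53bp2, Litaf, Ubxn1, Cwc22, Ankub1 and Ttc8 fell, with log2 fold changes of -0.37, -0.36, -0.26, -0.31, -0.36, -0.57, -0.27, -0.33, -1.18 and -0.22.

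Myelin genes fell as a list, with 16 of 16 negative, a median of -0.55 and a camera adjusted p of 2.23e-13 (adjusted p = 0.663 with an estimated correlation). Without Control+c-MSST replicate 6 the median was -0.37, and the difference in score went from -0.62 (exact permutation p = 0.0281, adjusted p = 0.114 over 32 score tests chosen after the data were seen) to -0.36 (exact permutation p = 0.0810, outside that adjustment). Adjusted over the list alone 15 were lower, against 0 over all genes. Mbp, a main protein of myelin, stood at 1064 ± 369 CPM (n = 5) against 1628 ± 330 CPM (n = 6; log2 fold change -0.61, SE 0.22, adjusted p = 0.176). Choroid plexus and ependymal markers fell (12 of 12 negative, median -2.07, camera adjusted p = 2.53e-06; adjusted p = 0.663 with an estimated correlation), together with the high Ttr of Control replicates 2 and 3. The other 10 lists named next passed camera but not with an estimated correlation (adjusted p = 0.663 to 0.728). Presynaptic genes such as Snap25 and Bsn (0.30, SE 0.08) were higher in 11 of 16 (median 0.10) and postsynaptic scaffold genes in 14 of 16 (0.09). Astrocyte markers were lower in 12 of 12 (median -0.14), and oligodendrocyte precursor markers in 10 of 12 (-0.17). Interferon response genes were lower in 18 of 19 (-0.61), antigen presentation genes in 12 of 14 (-0.40), fibroblast markers in 14 of 15 (-0.30) and proliferation genes in 15 of 16 (-0.25). Upper layer neuron markers were higher in 8 of 10 (0.16) and endothelial markers in 9 of 14 (0.11). By camera the adjusted p was 0.00101 for presynaptic and for astrocyte genes, 0.00197 for postsynaptic genes and 0.00201 for interferon genes. It was 0.00459 to 0.0303 for the rest. Il33 was the only called member of the cytokine list and Dnajb1 (0.26, adjusted p = 0.0439) of the heat shock list.

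The calls of the 54 genes depended on single libraries more than their size did: their median log2 fold change, signed by direction, was 0.35 with all libraries and 0.30 to 0.37 with any 1 library of these groups left out. The genes were chosen on the same libraries, so these folds do not test the calls anew. Leaving out an SCZ or SCZ+c-MSST library, which is outside this comparison, left 13 to 35 of the 54 called. Without Control+c-MSST replicates 6, 4, 7 and 1 edgeR called 0, 3, 4 and 128 genes, and without Control replicates 2, 4, 3, 5 and 7 it called 7, 18, 35, 31 and 318. DESeq2 called 567 genes, limma voom 8 and a fit of only these groups 0. Limma on FPKM values called 284 to 296, of which 95.6% to 98.2% were higher against 70.4% by edgeR. On FPKM values the median log2 fold change of all genes was itself 0.0228 to 0.0639, where by edgeR it was -0.0114. Whether this shift of all genes gave the excess of higher calls was not tested. Without Control replicates 2 and 3 together, chosen after seeing the data, edgeR called 16, of which 9 were among the 54. With the septal score as a covariate it called 4, and with the 3 tissue scores 0. The median signed log2 fold change of the 54 genes was then 0.35 and 0.28. With the 3 tissue scores as covariates, also chosen after seeing the data, 8 of the 12 lists no longer passed (0.240 to 0.982), while myelin, interferon, antigen presentation and endothelial genes did. The choroid plexus list could hardly pass there, because its own genes make up the choroid plexus score. Of the lists, interferon and antigen presentation were lost without Control replicate 4 (adjusted p = 0.263 for both). Fibroblast markers were lost without Control+c-MSST replicate 6 (0.220) and Control replicate 3 (0.285), and oligodendrocyte precursor markers without Control+c-MSST replicate 6 (0.0630). Upper layer markers were lost without Control+c-MSST replicate 1 (0.0583) and Control replicates 2 and 3 (0.0548 and 0.0564), and antigen presentation without Control+c-MSST replicate 2 (0.0522) and Control replicates 5 and 7 (0.0967 and 0.0901). Endothelial markers were lost without Control+c-MSST replicates 1, 2 and 7 (0.152, 0.0636 and 0.0812) and Control replicates 4 and 7 (0.107 and 0.0614). Proliferation genes were lost without Control+c-MSST replicates 1 and 6 (0.170 and 0.220) and Control replicates 1, 4 and 5 (0.130, 0.0554 and 0.0967).

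**Figure D3:**
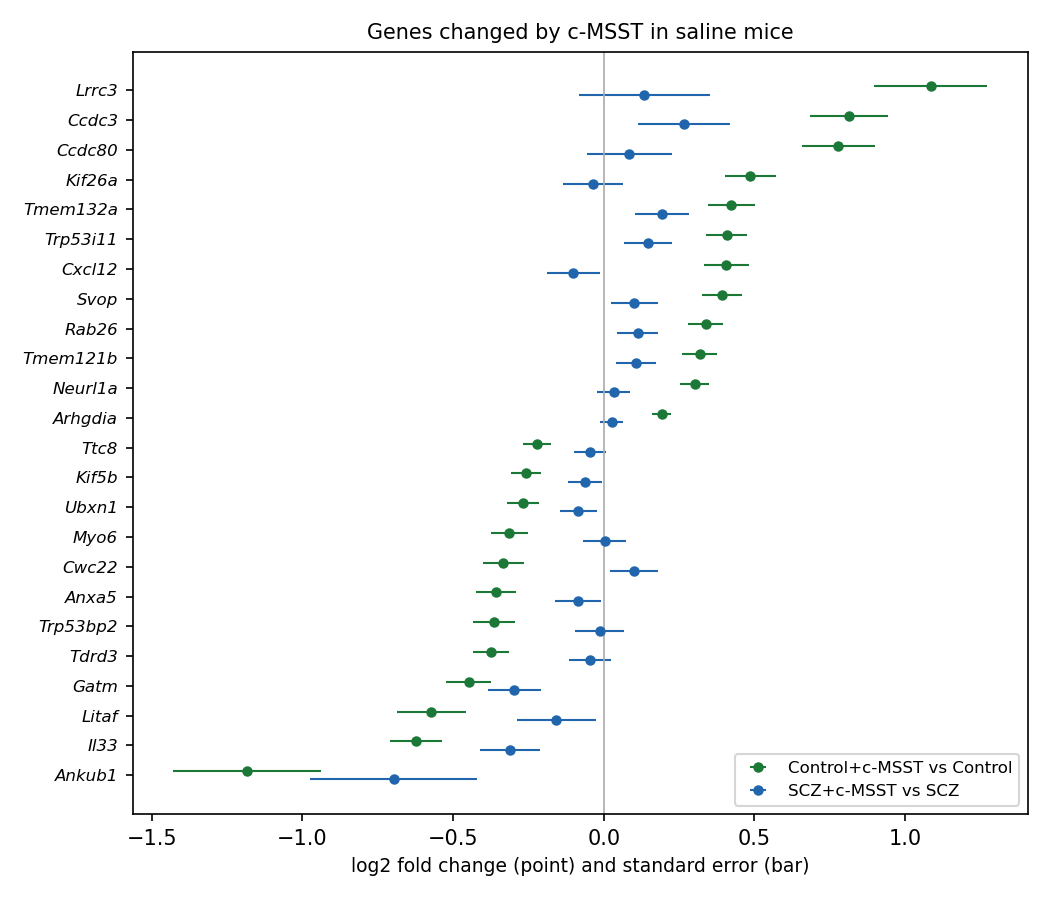
Points are log2 fold changes from edgeR with SE bars for the 24 named genes, for Control+c-MSST against Control and for SCZ+c-MSST against SCZ. All 24 passed in Control+c-MSST against Control, where 54 genes passed, and 0 passed in SCZ+c-MSST against SCZ.

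The comparison of SCZ+c-MSST with SCZ asks what c-MSST changed in MK-801 mice, and the series title names Gabre. Gabre encodes the epsilon subunit of the GABA-A receptor and lies on the minus strand of chromosome X at 72255999 to 72274803 (mm10), with 3 annotated transcripts. Its counts were 19, 16, 80 and 108 in SCZ replicates 1, 2, 3 and 5 and 0, 5, 0 and 4 in SCZ+c-MSST replicates 2, 3, 4 and 5, or 0.711 ± 0.535 CPM (SD, n = 4) against 0.0308 ± 0.0361 CPM (n = 4). The zeros allow up to 0.0447 and 0.0448 CPM in replicates 2 and 4. Control held 0.150 ± 0.107 CPM (n = 6) and Control+c-MSST 0.138 ± 0.165 CPM (n = 5). The edgeR log2 fold change was -4.42 (SE 1.29, adjusted p = 0.401) in SCZ+c-MSST against SCZ and 2.22 (SE 0.98, adjusted p = 0.331) in SCZ against Control. It was -2.20 (SE 1.21, adjusted p = 0.553) in SCZ+c-MSST against Control and -0.15 (SE 0.97, adjusted p = 0.965) in Control+c-MSST against Control, and none passed the threshold. With the septal score as a covariate, chosen after seeing the data, it was 0.80 in SCZ against Control and -2.78 (SE 1.37) in SCZ+c-MSST against SCZ. The exact permutation p, two-sided, was 0.0286 in SCZ+c-MSST against SCZ, the smallest that 4 against 4 libraries allow, and 0.0190 in SCZ against Control, both 0.0571 after adjustment over the 4 tests. It was 0.0905 in SCZ+c-MSST against Control and 0.558 in Control+c-MSST against Control.

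Other subunits of the receptor moved less in SCZ+c-MSST against SCZ. Gabrq, the theta subunit, stood at 1.66 ± 0.511 CPM (n = 4) against 4.65 ± 2.66 CPM (n = 4) in SCZ (log2 fold change -1.49, SE 0.52, edgeR adjusted p = 0.513). It stood at 2.28 ± 1.45 CPM in Control (n = 6) and 1.15 ± 0.234 CPM in Control+c-MSST (n = 5). Gabrg1 stood at 23.4 ± 4.58 CPM in SCZ+c-MSST, 32.0 ± 5.82 CPM in SCZ and 20.2 ± 4.42 CPM in Control (SCZ against Control 0.67, SE 0.15, adjusted p = 0.148). Adjusted over the list alone, 1 subunit passed in SCZ+c-MSST against SCZ (Gabre, edgeR adjusted p = 0.0460) and 1 in SCZ against Control (Gabrg1, adjusted p = 0.00582), against 0 over all genes. Because the series title names Gabre, its value over the list is not taken as independent evidence. The list of 16 subunits did not pass camera in SCZ+c-MSST against SCZ (adjusted p = 0.282, 8 of 16 negative). Nor did it pass in Control+c-MSST against Control (0.896, where the median was -0.07 and the test pointed up), in SCZ+c-MSST against Control (0.523) or in the interaction (0.403). Gabra6, Gabrp and Gabrr3 had too few counts to be tested.

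**Figure D4:**
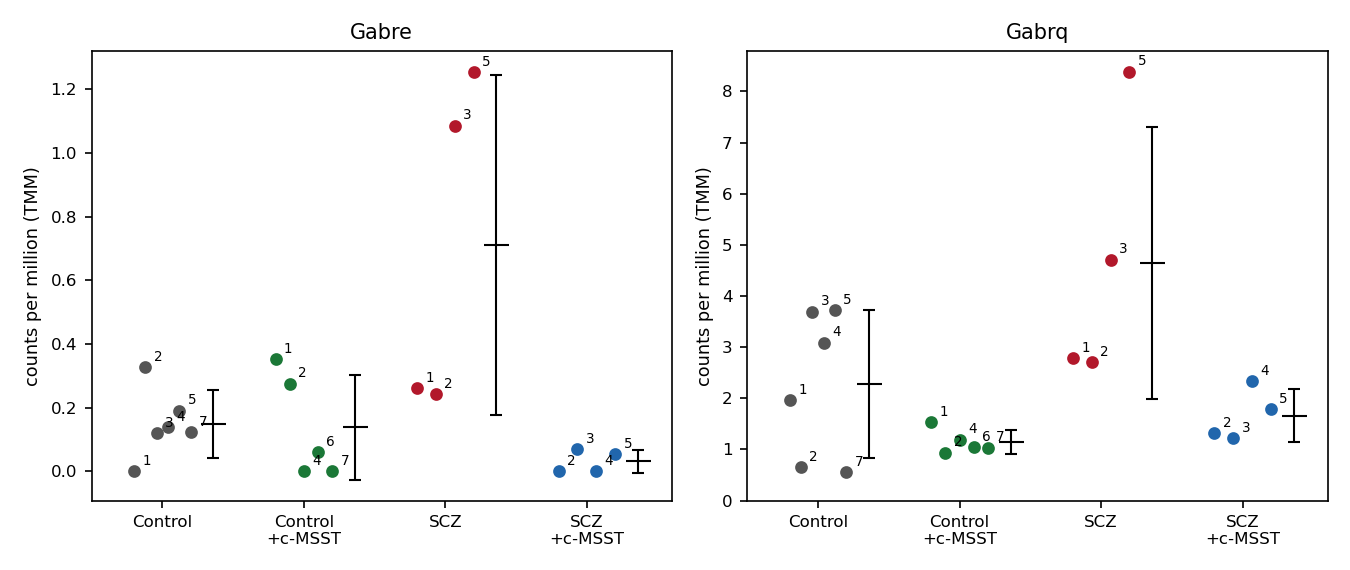
Each point is the CPM of Gabre or Gabrq in 1 library by group, with bars for the mean ± SD. Gabre averaged 0.711 CPM in SCZ and 0.0308 CPM in SCZ+c-MSST.

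Immediate early genes rose as a list in SCZ+c-MSST against SCZ, with 18 of 19 positive, a median of 0.42 and a camera adjusted p of 1.36e-12 (adjusted p = 0.276 with an estimated correlation). By library, their score differed by 0.47 (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.114 over the score tests). Dusp1, a phosphatase of MAP kinases named after its values were seen, stood at 41.2 ± 8.77 CPM (n = 4) against 15.9 ± 1.82 CPM (n = 4) in SCZ and 26.4 ± 5.84 CPM (n = 6) in Control. Npas4 had the opposite sign (-1.42, SE 0.44, adjusted p = 0.432). Egr1 had a log2 fold change of 0.21 (SE 0.19) and Homer1 of 0.22 (SE 0.12). Corticosteroid response genes rose (11 of 14 positive, median 0.27, camera adjusted p = 2.37e-10; adjusted p = 0.0873 with an estimated correlation), among which Klf9 stood at 277 ± 12.8 CPM against 235 ± 30.6 CPM. The corticosteroid score differed by 0.36 (exact permutation p = 0.0571, adjusted p = 0.183 over the score tests). The 7 lists that follow also passed camera but not with an estimated correlation (adjusted p = 0.276 to 0.729). Postsynaptic scaffold genes such as Camk2a and Shank1 were higher in 16 of 16 (median 0.11), presynaptic genes in 15 of 16 (0.13), apoptosis genes in 15 of 18 (0.07) and red blood cell genes in 7 of 8 (1.33). Ribosomal protein genes were lower in 70 of 75 (median -0.08), choroid plexus markers in 12 of 12 (-0.72) and myelin genes in 16 of 16 (-0.26). The septal score was lower as well (-0.14 ± 0.11 against 0.87 ± 0.58, exact permutation p = 0.0286, the smallest possible, adjusted p = 0.114 over 32 score tests chosen after the data were seen).

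By edgeR, 0 of 16417 genes passed in SCZ+c-MSST against SCZ, with 1241 at an unadjusted p under 0.05 (634 higher, 607 lower) and the smallest adjusted p at 0.0914, for Dusp1. DESeq2 called 62 genes, limma voom 46, a fit of only these groups 31 and limma on FPKM values 1 to 2. Without SCZ+c-MSST replicate 2 edgeR called 2 genes and without SCZ replicate 3 it called 1. Libraries outside the comparison mattered too. Dusp1 passed without Control+c-MSST replicate 1 or 2 or Control replicate 1 (edgeR adjusted p = 0.0411, 0.0247 and 0.0404). Cops2 passed without Control+c-MSST replicate 7 (0.00251). Adjusted over the list alone, 5 immediate early genes were higher and 1 was lower (Npas4), and 7 corticosteroid response genes were higher, against 0 over all genes. By camera the adjusted p was 2.43e-06 for ribosomal protein genes, 1.41e-05 for postsynaptic genes and 0.000129 for presynaptic genes. It was 0.00226 for choroid plexus, 0.00428 for myelin, 0.00880 for red blood cell genes and 0.0249 for apoptosis genes. The call was lost for red blood cell genes without SCZ+c-MSST replicate 2 (0.219) or SCZ replicate 3 (0.0530), and for myelin without SCZ+c-MSST replicate 4 (0.0837). It was lost for apoptosis genes without SCZ+c-MSST replicates 4 and 5 (0.0630 and 0.0849) or SCZ replicates 2 and 3 (0.0551 and 0.0530). With the septal score as a covariate, chosen after seeing the data, ribosomal, presynaptic, choroid plexus and myelin genes no longer passed (0.947, 0.526, 0.276 and 0.861). With the 3 scores 7 of the 9 lists no longer passed (0.0706 to 0.984), all but immediate early and corticosteroid response genes. Among the 7, the choroid plexus list could hardly pass, because its own genes make up the choroid plexus score.

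The comparison of SCZ+c-MSST with Control asks where the treated MK-801 mice stood against untreated saline mice. The 7 lists that follow passed camera, and none held with an estimated correlation (adjusted p = 0.860 for each) or with the striatal, septal and choroid plexus scores as covariates, chosen after seeing the data (adjusted p = 0.0828 to 0.966). The striatal and choroid plexus lists could hardly hold with these scores, because their own genes make up the scores of the same names. Striatal markers were higher in 12 of 12 (median 0.90, adjusted p = 1.13e-06), together with the striatal score of MK-801 mice, and red blood cell genes in 8 of 8 (1.14, adjusted p = 0.00628). Choroid plexus markers were lower in 12 of 12 (median -1.80, adjusted p = 5.55e-05), fibroblast markers in 15 of 15 (-0.27, adjusted p = 0.0119) and astrocyte markers in 10 of 12 (-0.08, adjusted p = 0.0116). Microglia markers such as Csf1r were higher in 12 of 14 (0.14, adjusted p = 0.00885) and ribosomal protein genes in 49 of 75 (0.04, adjusted p = 0.0358). The scores of immediate early genes averaged 0.07 ± 0.18 (SD, n = 4) in SCZ+c-MSST and 0.12 ± 0.31 (n = 6) in Control. By edgeR 0 genes passed, with 1655 at an unadjusted p under 0.05 (718 higher, 937 lower) and the smallest adjusted p at 0.0955. DESeq2 called 92, limma voom 0 and limma on FPKM values 0. Without SCZ+c-MSST replicate 5 or Control replicate 1 edgeR called 1. Calls were lost for red blood cell genes without SCZ+c-MSST replicate 2 (0.220), fibroblast markers without SCZ+c-MSST replicate 3 (0.231) or Control replicate 3 (0.459), and microglia without SCZ+c-MSST replicate 4 (0.157) or Control replicate 3 (0.104). They were lost for astrocyte markers without SCZ+c-MSST replicate 5 (0.0540) or Control replicate 2 (0.0578), and ribosomal genes without SCZ+c-MSST replicates 3 and 4 (0.397 and 0.272) or Control replicates 1, 2 and 7 (0.671, 0.0667 and 0.187).

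The interaction asks whether c-MSST acted differently in MK-801 and saline mice. Corticosteroid response genes moved up more with c-MSST in MK-801 mice (11 of 14 positive, median 0.34, camera adjusted p = 3.04e-07, adjusted p = 0.270 with an estimated correlation), as did immediate early genes (17 of 19, median 0.55, 1.06e-06, adjusted p = 0.875 with an estimated correlation). Myelin genes were positive in 16 of 16 (median 0.33, adjusted p = 0.00115), astrocyte markers in 11 of 12 (0.12, adjusted p = 0.0128) and interferon response genes in 16 of 19 (0.60, adjusted p = 0.0253). Endothelial markers were negative in 12 of 14 (-0.27, adjusted p = 0.000768). These lists had adjusted p = 0.513 to 0.941 with an estimated correlation. By edgeR 0 genes passed, with 1196 at an unadjusted p under 0.05 (640 higher, 556 lower) and the smallest adjusted p at 0.242. DESeq2 called 40, limma voom 0 and limma on FPKM values 0, and without SCZ replicate 3 edgeR called 1. Adjusted over the list alone, 7 corticosteroid response genes were higher, and 3 immediate early genes were higher and 1 lower. Calls were lost for myelin without Control+c-MSST replicate 6 (0.197), astrocyte markers without Control replicate 2 (0.0518). They were lost for interferon genes without SCZ+c-MSST replicate 4 (0.430), SCZ replicate 2 (0.158), Control+c-MSST replicates 1 and 4 (0.0501 and 0.0645) or Control replicates 4 and 7 (0.533 and 0.112).

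Across genes, which are not independent replicates, the fold changes of c-MSST in saline and in MK-801 mice, which share no library, had Pearson r = 0.179 by edgeR. Leaving out 1 library it ran from 0.0837 to 0.203. On log2 CPM r was 0.171, where simulated groups without effect gave 0.0025 (permutation p = 0.0135, two-sided). At an unadjusted p under 0.05, 118 genes were higher in both, where 49.8 are reached by chance, and 88 lower in both, where 52.8 are. Of the 54 genes, 48 had the same sign in SCZ+c-MSST against SCZ, 6 of them at an unadjusted p under 0.05, Il33 (-0.31), Gatm (-0.30) and Ankub1 (-0.70) included. The fold changes of SCZ against Control and of SCZ+c-MSST against SCZ share the 4 SCZ libraries and had r = -0.469 by edgeR. On log2 CPM r was -0.4996, where simulated groups without effect that share libraries gave -0.544 (permutation p = 0.744, one-sided), and the covariance was -0.0717 where they gave -0.0613. With the SCZ libraries split so that none was shared, r averaged -0.119 and ran from -0.138 to -0.0873 over 6 ways, which reuse the same libraries and were not tested. The fold changes of SCZ and of Control+c-MSST, both against Control, had r = 0.320 by edgeR. On log2 CPM r was 0.264, where simulated groups gave 0.430 (permutation p = 0.954, one-sided).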

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

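The tests of explanations in this part, and the splits of the libraries, were chosen after the results they address were seen; the tests of the interaction were planned. Immediate early and corticosteroid response genes were lower in SCZ than in Control and higher in SCZ+c-MSST than in SCZ, and both comparisons share the 4 SCZ libraries. Neighbouring tissue in some samples stays open as a cause. With the striatal, septal and choroid plexus scores as covariates, chosen after seeing the data, the largest of the 4 camera adjusted p values was 1.95e-05. The immediate early medians were then -0.42 and 0.47 (-0.61 and 0.42 without covariates), and the corticosteroid medians -0.28 and 0.22 (-0.43 and 0.27 without). Both shifts thus remained in this model. However, the septal and the choroid plexus score each separated all SCZ+c-MSST from all SCZ libraries (exact permutation p = 0.0286 for each, adjusted p = 0.114). Tissue and treatment therefore cannot be told apart in that comparison, and tissue outside these scores was not tested. With the septal score alone, only 8 of 14 corticosteroid genes were positive in SCZ+c-MSST against SCZ (11 without covariates). Tissue taken at another time of day stays open. The median absolute log2 fold change of 15 clock genes, Per1 left out, was 0.123 in SCZ+c-MSST against SCZ, where that of immediate early genes was 0.462. In SCZ against Control these medians were 0.0876 and 0.627, and the largest shift of a clock gene was 0.39, for Per2. How far clock genes and these lists move with the hour was not measured here, so the smaller clock shift does not decide. Handling shortly before tissue was taken stays open, because the mean immediate early score differed by -0.529 where the Control libraries alone spanned 0.866. An effect of MK-801 and of c-MSST, its surgery included, on neuronal activity also stays open, and no list call held with an estimated correlation. Nor did the exact permutation tests of these scores pass after adjustment (adjusted p = 0.114 to 0.183).

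Gabre was lower in SCZ+c-MSST than in SCZ, on 4 libraries each and few counts. Tissue that carries Gabre in proportion to Zic1 stays open: Zic1 was above 30 CPM in 3 SCZ, 3 Control and 0 SCZ+c-MSST libraries, and among these Gabre per Zic1 did not separate SCZ from Control in a test that cannot go below 0.1 (exact permutation p = 0.2). Striatal tissue is argued against as the cause, since the log2 fold change was -4.35 (SE 1.29) with the striatal score as a covariate and -4.42 (SE 1.29) without. Other differences in the region dissected stay open too: with the septal score as a covariate the log2 fold change was -2.78 (SE 1.37, adjusted p = 1.00), and that score itself separated the groups (exact permutation p = 0.0286), so region and treatment cannot be told apart here. An effect of c-MSST, its surgery included, on Gabre also stays open, and over 21 alternatives and left-out libraries on the counts its adjusted p ran from 0.0704 to 1.00.

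Myelin genes were lower, and 54 genes changed, in Control+c-MSST against Control. Choroid plexus tissue in Control replicates 2 and 3 is argued against as the whole cause for the myelin genes, since without both libraries their median log2 fold change was -0.59 (-0.55 with them). For the 54 genes it stays open. Their median signed log2 fold change was 0.31 without both (median SE 0.069) and 0.35 with them (SE 0.067), and with 4 Control libraries only 16 genes were called. With the 3 tissue scores as covariates none was called, and this median was 0.28 (SE 0.075). The 54 genes were chosen on the same libraries, which favours genes whose folds hold when a library is left out, so these folds do not decide. Less white matter in Control+c-MSST replicate 6 stays open for the 54 genes for the same reason. Their median signed log2 fold change was 0.30 without it (median SE 0.065). None was then called (smallest adjusted p 0.0717), and beyond the lower folds why the calls ended was not tested. For the myelin genes less white matter in this replicate stays open too, because without it their median was -0.37 where it was -0.55 with it. The share of white matter in the dissections as a whole, an effect of c-MSST, and an effect of surgery and injection, which the labels do not state for the groups without c-MSST, stay open and were not tested.

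Other splits of the same libraries were set against each comparison. For SCZ against Control, 2 of 100 splits, the real one included, gave as many as 2219 genes at an unadjusted p under 0.05 (highest of the others 2390). For Control+c-MSST against Control 3 of 100 gave as many as 54 changed genes, and 1 of 100 as many as 2718 genes at an unadjusted p under 0.05 (highest of the others 2442). For SCZ+c-MSST against SCZ 1 of 35 gave as many as 1241 (highest of the others 965). The share of such splits was under 0.05 for each of these counts, without adjustment over the counts. For SCZ+c-MSST against SCZ it was the smallest that 35 splits allow. Since the splits were also chosen after the results were seen, chance was not excluded. For changed genes in SCZ against Control or SCZ+c-MSST against SCZ the splits cannot decide, because the real count was 0 by edgeR. All 100 and all 35 splits therefore gave as many, and others called up to 223 and 1. In Control+c-MSST against Control, 19 of 100 splits, the real one included, called a gene. One of the other splits of the Control+c-MSST comparison called 305 genes, several times the real count. Why that split called so many was not tested. The share was above 0.05 for SCZ+c-MSST against Control, where 17 of 100 splits gave as many as 1655 genes (highest of the others 2806), and for the interaction, where 11 of 100 gave as many as 1196 (highest of the others 1997).

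In 15 of 260 groups of libraries tested, 1 library lay far from the others of its group, where chance gives 13. The gap to the nearest library, as a share of the range of the group, was as follows. It was 0.661 for Ccdc80 in Control replicate 3 (lowest), 0.808 for Arhgdia in Control+c-MSST replicate 1 (highest) and 0.889 in SCZ replicate 3 (lowest), and 0.856 for Kif26a in SCZ+c-MSST replicate 3 (lowest). It was 0.735 for Tmem121b in Control+c-MSST replicate 6 (highest), 0.831 for Tmem132a in SCZ replicate 5 (lowest) and 0.862 for Ankub1 in SCZ replicate 5 (highest). Among receptor subunits it was 0.650 for Gabre in Control replicate 1 (lowest, at 0 counts) and 0.673 for Gabrr1 in Control replicate 4 (highest). Among scores it was 0.748 for postsynaptic genes in Control+c-MSST replicate 2 (lowest), 0.863 for astrocyte markers in SCZ replicate 5 (highest), 0.835 for corticosteroid response genes in SCZ+c-MSST replicate 3 (lowest), 0.880 for interferon response genes in SCZ+c-MSST replicate 4 (highest), 0.804 for red blood cell genes in Control+c-MSST replicate 7 (highest) and 0.658 for apoptosis genes in Control replicate 7 (lowest). The effect of c-MSST differed between MK-801 and saline mice, by the camera test of the interaction, for 6 lists. The adjusted p was 1.06e-06 for immediate early genes, 3.04e-07 for corticosteroid response genes, 0.000768 for endothelial markers, 0.00115 for myelin genes, 0.0128 for astrocyte markers and 0.0253 for interferon response genes. None held with an estimated correlation (adjusted p = 0.270 to 0.941).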

How the results depend on the processing

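Alternatives with tissue scores as covariates, without Control replicates 2 and 3 together, without the 114 genes near absent from some library and with the Control libraries split were chosen after seeing the data; the others were planned. No named gene changed sign where it was called, and no list call became a call in the other direction. List calls that were lost were not checked for a change of direction. Signs did change among uncalled values, namely Gabre in Control+c-MSST against Control, the correlation of the comparisons that share Control, and 178 values of other named genes. Where values moved and no construction is named, the cause was not tested. Genes called in SCZ against Control (0 by edgeR with TMM) were 243 by DESeq2, 2 with 1 surrogate variable, and 1 each with upper-quartile normalization, the 3 FPKM settings, the 3 tissue scores, and only the groups compared, mostly Cops2. Leaving out 1 library gave 0 to 94. Genes called in Control+c-MSST against Control (54) were 567 by DESeq2, 8 by voom, 0 with the replicate block, and 161 with 1 surrogate variable. They were 292, 296 and 284 on FPKM, 174 with the striatal score, 4 with the septal score, 0 with the 3 scores, 16 without Control replicates 2 and 3, 0 with only the groups compared, and 0 to 318 leaving out 1 library. The median log2 fold change of the 54 genes, signed by direction, moved less (0.35, median SE 0.067): it was 0.35 with the striatal score (SE 0.066), 0.35 with the septal score (SE 0.072), 0.28 with the 3 scores (SE 0.075), 0.31 without Control replicates 2 and 3 (SE 0.069), 0.31 with the block (SE 0.068), 0.35 with only the groups compared (SE 0.073) and 0.30 to 0.37 leaving out 1 library. These genes were chosen on the same libraries, so the folds do not test the calls anew. Genes called in SCZ+c-MSST against SCZ (0) were 62 by DESeq2, 46 by voom, 2, 2 and 1 on FPKM, 31 with only the groups compared and 0 to 2 leaving out 1 library. In SCZ+c-MSST against Control (0) it was 92 by DESeq2, 5 with 1 surrogate variable, 1 with the septal score, 1 with the 3 scores and 0 to 1. In the interaction (0) it was 40 by DESeq2, 1 without Control replicates 2 and 3 (B2m, 1.03) and 0 to 1. The log2 fold change of Gabre in Control+c-MSST against Control (-0.15) was 0.041 with the replicate block, 0.34 with 1 surrogate variable, 0.22 with the septal score, 0.80 with the 3 scores, 0.24 without Control replicates 2 and 3 and -0.83 to 0.23 leaving out 1 library. Its whole range there was -1.69 to 0.80. Over all alternatives on the counts it ran from 0.80 (septal score) to 2.61 in SCZ against Control, -5.11 to -2.50 (3 scores) in SCZ+c-MSST against SCZ, -3.15 to -1.27 in SCZ+c-MSST against Control and -4.96 to -2.93 in the interaction. Leaving out 1 library it was 1.79 to 2.60 in SCZ against Control, -5.11 to -4.00 in SCZ+c-MSST against SCZ, -2.89 to -1.82 in SCZ+c-MSST against Control and -4.96 to -3.60 in the interaction. It could not be tested at a mean of at least 1 CPM. Lists past camera (12, 12, 9, 7 and 6 in the 5 comparisons, in the order above) were 0 in each with an estimated correlation, 2, 0, 0, 0 and 0 by fry, 6, 4, 4, 0 and 10 with the 3 scores, and 7 to 14, 8 to 13, 7 to 10, 5 to 9 and 5 to 12 leaving out 1 library. Of the 46 list calls, 37 held with the striatal score, 33 with the septal score, 17 with the 3 scores and 35 without Control replicates 2 and 3. The striatal and choroid plexus lists could hardly hold with scores made of their own genes. The correlation of c-MSST fold changes (0.179) was 0.233 at a mean of at least 1 CPM, 0.136 with the block, 0.220 with the septal score, 0.299 with the 3 scores, 0.130 without Control replicates 2 and 3, and 0.0837 to 0.203. That of SCZ against its treatment (-0.469) was -0.119 with the SCZ libraries split, so that none was shared, and -0.591 to -0.372. That of the comparisons that share Control (0.320) was 0.261 with the striatal score, -0.0748 with the Control libraries split, and 0.234 to 0.403. Of the 24 named genes called in Control+c-MSST against Control, 0 kept their call with the block, with only the groups compared or with the 3 scores, 4 with the septal score and 8 by voom. The replicate numbers did not pair the libraries: 19 same-number pairs had a mean correlation of -0.0192 and 115 other pairs 0.00316. At a log2(FPKM + 0.1) scale the median of all genes moved by -0.125 in the interaction. Gabre, at 0 to 108 counts, is limited by depth, since a count of 0 allows up to 0.0447 CPM in SCZ+c-MSST replicate 2.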

Other observations

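The haemoglobin genes of red blood cells split the libraries in a way that did not follow the groups. Hbb-b1 stood under 1 CPM in 5 libraries (SCZ+c-MSST replicates 2 and 3, Control+c-MSST replicate 2, Control replicates 4 and 5), where Hbb-bs stood at 60.1 CPM or more. In the other 14 libraries Hbb-b1 stood at 47.5 to 199.7 CPM and Hbb-bs at 8.24 CPM or less. Hba-a1 had at most 2 counts in 11 libraries. These genes have near-identical copies, so the assignment of reads between them is uncertain, and the red blood cell list holds several of them. Why the libraries split in this way was not tested, and the labels give no strain.

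Cops2 stood at 90.5 ± 4.65 CPM (SD, n = 4) in SCZ, 58.9 ± 4.74 CPM (n = 6) in Control and 58.4 ± 5.28 CPM (n = 4) in SCZ+c-MSST. Its log2 fold change by edgeR was 0.62 (SE 0.10, adjusted p = 0.0649) in SCZ against Control and -0.63 (SE 0.11, adjusted p = 0.0973) in SCZ+c-MSST against SCZ, which share the SCZ libraries, and the gene was chosen after its values were seen. It passed in both without Control+c-MSST replicate 7 (edgeR adjusted p = 0.000731 and 0.00251), a library outside these comparisons. Interferon response genes had their highest Control score in Control replicate 4 (1.36). Lhx8, a marker of basal forebrain neurons, stood highest in SCZ replicate 5 (7.34 CPM).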
